A study of Mus musculus with 8 samples.

How the data were processed

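Gene expression was measured on 8 single-channel oligonucleotide arrays, 1 for each RNA sample. The samples were CD4+CD25+ cells sorted from mouse spleen and peripheral lymph nodes, 4 from wild-type mice (WT) and 4 from mice in which a Cre recombinase driven by Cd4 deletes a floxed Rptor gene (RaptorKO), per the labels. Cells were used without treatment after sorting, and total RNA was converted into biotinylated cDNA, per the labels' protocols. The deposited values are log2 intensities for each probe set, made with the robust multi-array average (RMA), per the submitters' processing notes; the version is not given in the sources used here. As usually run, RMA subtracts background, normalizes between arrays and summarizes the probes of a set on the log2 scale, which removes differences between arrays in total signal. On every array the median lay between 5.21 and 5.29, and no further normalization was applied. The number of arrays limits the precision. Group and replicate number were taken from the sample titles. The labels do not say whether the samples of a group came from separate mice, so p-values measure the spread between these samples, which may be partly technical.

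The value table held 45141 probe sets, 104 of them array controls. Gene names came from the platform's annotation, updated through Entrez identifiers to current mouse symbols with a RefSeq gene table of assembly GRCm38.p6; 28689 of the 28898 probe sets with a single gene matched. A further 551 probe sets listed several genes and were not named, and 15692, controls included, listed none. Each of 17097 genes was represented by the probe set with the highest mean over all 8 arrays. A probe set was tested if it exceeded its array's 40th percentile on at least 4 arrays, which left 11413 genes. The array names no genome build, so no coordinates are given.

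RaptorKO was compared with WT with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates, 4 arrays against 4), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Changes are RaptorKO minus WT on the log2 scale with the standard error (SE) of the fit. All adjusted p-values for genes below come from this limma fit over 11413 genes unless another fit is named. Gene lists, 35 in all, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 35 lists, and again with the correlation estimated from the data. For each list the number of called members is given over all genes and adjusted over the list alone. The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule took Rptor, then Foxp3, Il2ra, Ctla4, Icos, Cd4, Myc and Sqle, then the 8 largest changes in each direction among called genes whose groups did not overlap, leaving out predicted or clone-named genes. It also took up to 4 called members of each list by smallest p or, where none was called, 2 members with the smallest p, as values. A further gene that the rule named is not reported here.

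The alternatives were a replicate block, the mean of a gene's probe sets, all probe sets tested separately, no filter or a 60th percentile filter, quantile normalization, centring of each array on its median or 75th percentile, an intensity trend or robust variance in eBayes, array weights, a 1.5-fold minimum, leaving out each array, and, for lists, the estimated correlation and fry. Chosen after seeing the data were a term for replicates 1 and 2 against 3 and 4, fits within each of these sets, and a covariate for macrophage markers. The scripts were tested on simulated data, 4 arrays against 4, with the real means of the 11413 genes. The simulated spread of each gene was its real spread drawn partly toward the median spread, so the shares that follow hold for that setting. Of 100 genes changed by 1 on the log2 scale, 100% were called, and of 100 changed by 0.5, 26% were called; 5.97% of calls were false. Camera called 1 list when 1 was shifted by 0.3 and 0 when nothing was changed. The simulated genes varied independently, so this could not show false calls of lists that come from correlation between genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.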

Results

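Regulatory T cells, the CD4 T cells that restrain immune responses, were profiled as sorted CD4+CD25+ cells from WT mice and from mice lacking Rptor in T cells, with 4 arrays in each group. Rptor encodes Raptor, the scaffold protein that defines the kinase complex mTORC1. The comparison asks which transcripts differ in these cells when Raptor is deleted, with metabolism and immune function as the stated interests of the study. Array medians lay between 5.21 and 5.29 on the log2 scale. The leading principal component held 26.2% of the variance and separated the genotypes, while the next held 25.55% and mainly separated RaptorKO 1 and 2 from RaptorKO 3 and 4.

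The targeted gene, Rptor, had a mean log2 value of 6.86 ± 0.12 (SD, n = 4) in WT and 6.64 ± 0.22 in RaptorKO, a difference of -0.23 (SE 0.12, adjusted p = 0.491) that did not pass the test. In WT 1 to WT 4 the values were 6.83, 6.85, 7.03 and 6.75, and in RaptorKO 1 to RaptorKO 4 they were 6.63, 6.47, 6.50 and 6.95. A dimmer Rptor probe set read 5.98 ± 0.11 in WT and 5.56 ± 0.15 in RaptorKO, a change of -0.42 (limma with every probe set tested, adjusted p = 0.147). Both probe sets had a lower mean in RaptorKO. In limma with every probe set tested, the unadjusted p was 0.0933 for the brighter and 0.00242 for the dimmer. Where either probe set lies relative to the deleted part of the gene is not known here, so these values do not decide on the genotype labels.

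Eno2, an enolase isoform best known from neurons, rose by 2.39 (SE 0.19, adjusted p = 0.000137), or 5.25-fold, from 5.33 ± 0.40 in WT to 7.73 ± 0.28 in RaptorKO (SD, n = 4 each). Hpgds, which makes prostaglandin D2, rose by 2.18, and the collagen gene Col27a1 rose by 1.99. The lubricin gene Prg4 fell by 1.64, the sulfotransferase gene Chst2 fell by 1.47, and Nrp1, a semaphorin and growth factor receptor present on many regulatory T cells, fell by 1.44 (SE 0.15, adjusted p = 0.000736) or 2.72-fold. Gbp2b, an interferon-inducible GTPase, differed by -1.67 (adjusted p = 0.00226), but its RaptorKO values, 3.88 to 4.37, lay under the filter's percentile on all 4 arrays (4.69 to 4.81), so the size of the fall is measured against dim signal. Arhgap20 (1.83), the metallothionein Mt1 (1.76), the enkephalin precursor Penk (1.68), the ion channel Trpm1 (1.65) and the ubiquitin ligase Rnf157 (1.61) completed the 8 largest increases. On 3 of the 4 WT arrays Mt1 lay under the filter's percentile (4.31 to 4.73, against 4.74 to 4.79), so its rise too is measured against dim signal. With the mean of all probe sets of a gene the changes were 0.97 for Mt1, 0.88 for Rnf157 and -0.74 for Chst2, and each stayed called. Prg4 was not called within replicates 1 and 2 (adjusted p = 0.217) and differed by -2.28 within replicates 3 and 4, but the difference between these sets, -1.28, did not pass (limma interaction, adjusted p = 0.334). Trat1 (-1.30), Cyria (-1.29) and Rflnb (-1.23) were also among the 8 largest decreases taken by the rule, as was Fgl2 (-1.34), whose RaptorKO values of 3.71 to 4.29 lay under the filter's percentile on all 4 arrays too.

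In all, 224 of 11413 genes changed, 94 higher and 130 lower in RaptorKO (limma with Benjamini-Hochberg adjustment). Of these, 75 rose and 82 fell by at least 1.5-fold, and 30 rose and 18 fell by at least 2-fold. All 224 had groups that did not overlap, as did 1007 genes in total, or 8.82% against 2.86% by chance. Of the 35 gene lists, 8 were called with the preset correlation, 0 with an estimated correlation, 2 with fry, and 14 with the preset correlation without RaptorKO 2. Of the 35 splits of the arrays into 4 and 4, 14, the real one among them, called as many lists at the preset correlation. Chance is therefore not excluded for the number of list calls. Only cholesterol biosynthesis and mitosis were set against the splits singly. Leaving out single arrays lowered the count of changed genes to 123 without WT 1, 121 without WT 3, 102 without WT 4, 133 without RaptorKO 1 and 145 without RaptorKO 3. Genes higher numbered 62 without WT 2, 56 without WT 4 and 62 without RaptorKO 1, and genes lower 57 without WT 1, 55 without WT 3, 46 without WT 4, 71 without RaptorKO 1 and 62 without RaptorKO 3. Of 48 called genes named here, 18 lost the call without at least 1 array and are given below with those arrays. Replicates 1 and 2 of both genotypes carried a female pattern of sex-linked transcripts and replicates 3 and 4 a male pattern, as described further on; 11 genes changed in the former set alone, 128 in the latter, and 248 with a term for the 2 sets. With an intensity trend 370 changed (147 higher, 223 lower), and with array weights 205 were lower.

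**Figure D1:**
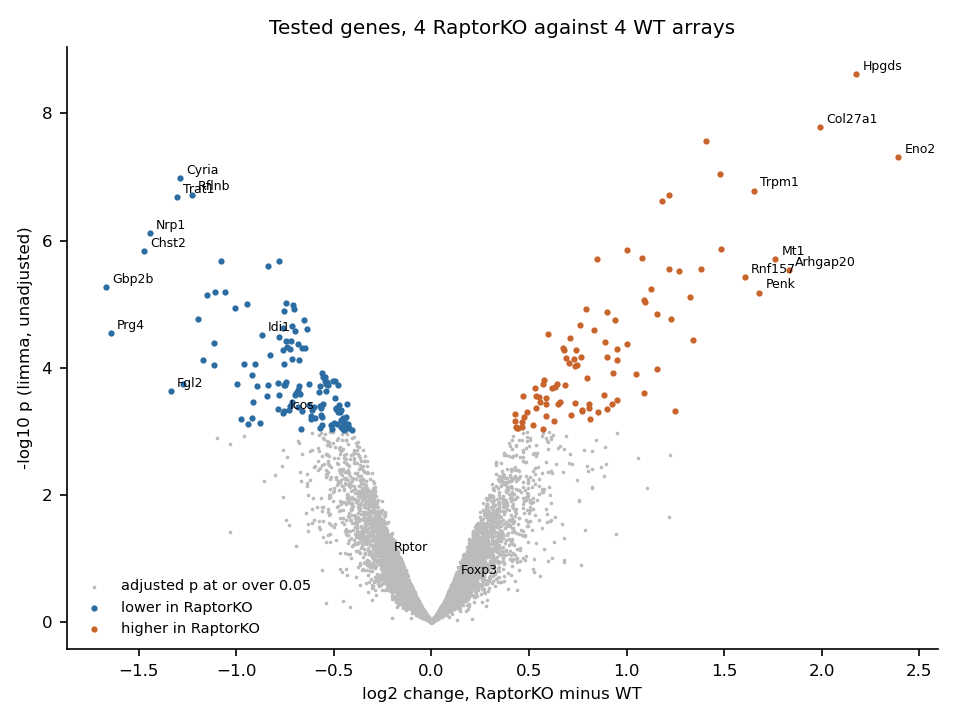
Change of each tested gene in RaptorKO against WT (x axis, log2) and its unadjusted limma p (y axis, -log10), with called genes coloured by direction. The 94 higher and 130 lower genes form the upper arms, and Rptor and Foxp3 lie among the genes that were not called.

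Several regulatory T cell genes changed in opposite directions while the lineage factor itself did not pass the test. Foxp3, the transcription factor that defines these cells, lay between 10.79 and 10.96 in WT and between 10.96 and 11.04 in RaptorKO (change 0.12, SE 0.09, adjusted p = 0.664), and Il2ra, the CD25 chain used for the sort, differed by 0.030 (adjusted p = 0.949). In the list of regulatory T cell identity genes, Penk and the signalling adaptor Swap70 (0.79) rose, and Nrp1 and Nt5e, the ectonucleotidase CD73 (-0.76), fell. These were 2 higher and 2 lower of 23 tested members, or 4 and 5 adjusted over the list alone. The median was -0.037 and the mean -0.0028 (camera adjusted p = 0.958).

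Among effector molecules of regulatory T cells, Icos, a costimulatory receptor, fell by 0.76 (SE 0.16, adjusted p = 0.0329), from 9.68 ± 0.27 to 8.92 ± 0.27 (SD, n = 4). The transcription factor Nfil3 (-1.19, with 1 RaptorKO array under the filter's percentile), the calcium-binding protein S100a6 (1.99-fold higher in WT) and the secreted fibrinogen-like protein Fgl2 (-1.34, with dim RaptorKO values) also fell, while the transcription factor Myb (0.95) rose. That made 1 higher and 4 lower of 33 tested members, or 3 and 8 adjusted over the list alone. The list had a median of -0.15 and did not pass camera (adjusted p = 0.0848, and adjusted p = 0.724 with an estimated correlation). Its median was 0.0052 in replicates 1 and 2 alone, and the list passed without WT 1 (-0.16, camera adjusted p = 0.0445) and without RaptorKO 4 (-0.16, camera adjusted p = 0.0146). The median was -0.027 without WT 4 (camera adjusted p = 0.632) and -0.091 without RaptorKO 3 (camera adjusted p = 0.272). Icos was not called without WT 2, WT 3, WT 4, RaptorKO 1 or RaptorKO 3, with adjusted p = 0.105 as the highest (-0.66 without WT 4). S100a6 lost its call without WT 2, WT 4 (adjusted p = 0.0688), RaptorKO 1 or RaptorKO 3, and Fgl2 without RaptorKO 1 or RaptorKO 3 (-1.23, adjusted p = 0.0608). Fgl2 passed the filter on the WT arrays only, so it was not tested where a WT array was left out. Ctla4, an inhibitory receptor, differed by -0.32 (SE 0.10, adjusted p = 0.169), and Cd4 by -0.22 (adjusted p = 0.362).

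**Figure D2:**
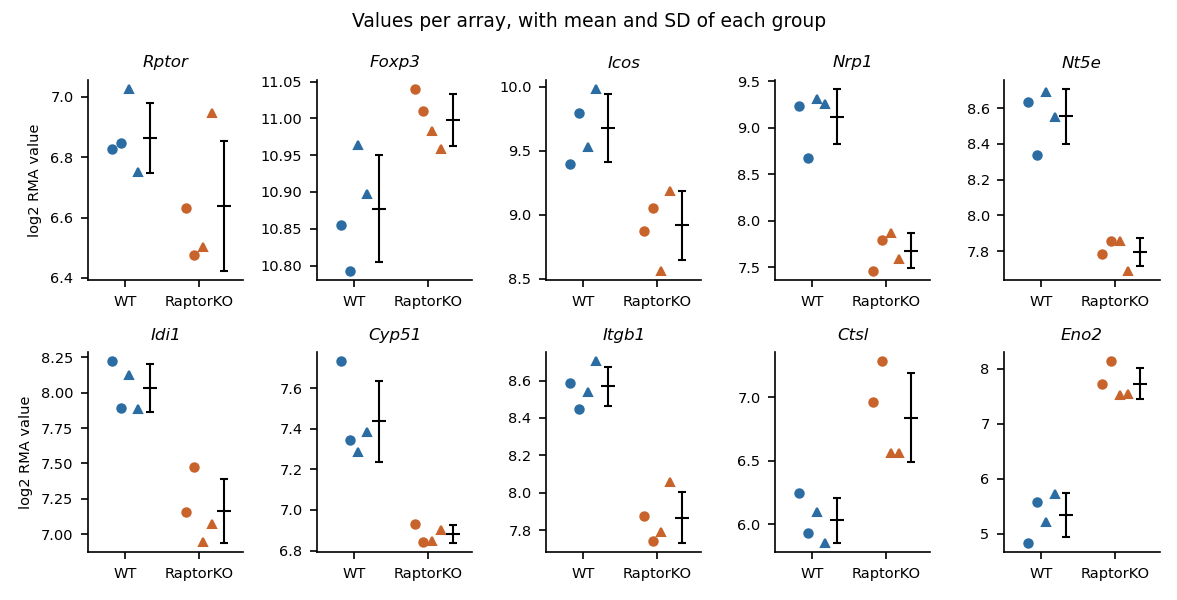
Log2 values of 10 genes on each array, with circles for replicates 1 and 2, triangles for replicates 3 and 4, and bars for the mean and SD of 4 arrays; y axes do not start at 0. Icos, Nrp1, Nt5e, Idi1, Cyp51 and Itgb1 lie lower on every RaptorKO array, Ctsl and Eno2 lie higher, and the Rptor and Foxp3 groups overlap.

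Transcripts of cholesterol biosynthesis were lower in RaptorKO. Idi1, the isopentenyl diphosphate isomerase, fell by 0.87 (SE 0.13, adjusted p = 0.00613), from 8.03 ± 0.17 to 7.16 ± 0.23 (SD, n = 4), and Cyp51, the lanosterol demethylase, fell by 0.56 (SE 0.11, adjusted p = 0.0284). All 17 tested members had a negative change, with a median of -0.37; 2 were called over all genes and 9 adjusted over the list alone. Sqle, the squalene epoxidase, differed by -0.52 (SE 0.17, adjusted p = 0.187). Its change was -0.22 within replicates 1 and 2 and -0.83 within replicates 3 and 4 (limma interaction, adjusted p = 0.452). The list had a camera adjusted p = 1.61e-08, and adjusted p = 0.218 with an estimated correlation. The list was also lower within replicates 1 and 2 (median -0.22, camera adjusted p = 0.000322) and within replicates 3 and 4 (median -0.40, camera adjusted p = 1.2e-05). Markers of conventional CD4 T cells (median -0.23, 14 of 16 negative) and of myeloid cells (median 0.24, 17 of 19 positive) also shifted between genotypes. With macrophage markers as a covariate the cholesterol median was -0.38 (camera adjusted p = 6.86e-08). That covariate also differs between replicates 1 and 2 and replicates 3 and 4. Cyp51 lost its call without WT 1 (-0.46, adjusted p = 0.0727), WT 2, WT 4 (-0.57, adjusted p = 0.0738), RaptorKO 1, RaptorKO 3 or RaptorKO 4.

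Other metabolic lists moved less. In glycolysis, Hif1a, the hypoxia-inducible regulator of the pathway, fell by 0.54 (adjusted p = 0.0209) and was the only called member of 17, with 1 higher and 3 lower adjusted over the list alone. The fixed list holds the enolase Eno1 but not Eno2, the enolase isoform that rose by 2.39. The glycolysis median was -0.15 (camera adjusted p = 0.0637). Fatty acid synthesis had 0 called members of 17, and 0 higher and 4 lower adjusted over the list alone, with a median of -0.093 (camera adjusted p = 0.0848). Acss2 differed by -0.67, with -0.22 within replicates 1 and 2 and -1.11 within replicates 3 and 4 (limma interaction, adjusted p = 0.334). It was called in 1 alternative (lowest limma adjusted p = 0.0486), and Acsl3 differed by -0.48. Psat1, an enzyme of serine synthesis, fell by 0.60 and was the only called member of 25 in the list of ATF4 targets and one-carbon metabolism, also adjusted over the list alone (median -0.14, camera adjusted p = 0.0637). The medians were -0.074 for the TCA cycle (Ogdh -0.38, Aco1 -0.55), -0.065 for oxidative phosphorylation (Ndufs1 -0.25, Atp5k -0.23), -0.016 for the pentose phosphate pathway and nucleotide synthesis (Dut 0.29, Ctps 0.24) and -0.0085 for fatty acid oxidation (Etfdh 0.29, Acaa2 0.11). None of these 4 lists had a called member over all genes or adjusted over the list alone, and camera gave adjusted p = 0.136, 0.0608, 0.958 and 0.958. Nucleotide synthesis had a mean of 0.0025 and a camera direction opposite to its median, and fatty acid oxidation a camera direction opposite to both median and mean. Mitochondrial biogenesis had 0 called members of 26 and 1 higher adjusted over the list alone (Ppargc1b 0.59, Hspa9 0.30; median 0.016, camera adjusted p = 0.165). Hif1a lost its call without any single array but WT 2 or RaptorKO 2 (highest adjusted p = 0.08, -0.50 without WT 3), and Psat1 without any but RaptorKO 1 or RaptorKO 2 (highest adjusted p = 0.104, -0.56 without WT 1). Without WT 2 or RaptorKO 2 several lists passed camera, with medians of -0.20 and -0.17 for glycolysis (adjusted p = 0.0286 and 0.0477), -0.14 and -0.11 for the TCA cycle, -0.12 and -0.14 for oxidative phosphorylation (adjusted p = 0.00319 and 0.000751) and -0.14 and -0.15 for ATF4 targets. The medians were smaller for the TCA cycle without WT 1 (-0.049) or WT 4 (-0.049, camera adjusted p = 0.556) and for oxidative phosphorylation without RaptorKO 3 (-0.030, camera adjusted p = 0.268). Fatty acid synthesis passed without WT 3 (-0.20) or RaptorKO 2 (-0.20). Oxidative phosphorylation had a median of 0.064 within replicates 1 and 2 and -0.21 within replicates 3 and 4 (camera adjusted p = 3.32e-05); the difference between these sets was not tested for lists.

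Regulators of mTORC1 and of translation changed singly. Rragd, a Rag GTPase of the amino acid sensing machinery, rose by 1.13 (SE 0.14, adjusted p = 0.00233), and Tsc1, which encodes an inhibitor of mTORC1, rose by 0.53; they were the 2 called members of 29, with 2 higher and 3 lower adjusted over the list alone (median 0.015, camera adjusted p = 0.663). Eef2k, the kinase that slows translation elongation, rose by 0.90 (0.54 with the mean of its probe sets) and was the only called member of 21 in its list, with 1 higher and 1 lower adjusted over the list alone (median 0.025, camera adjusted p = 0.332). Tsc1 lost its call without WT 2, WT 3, WT 4 (0.48, adjusted p = 0.107), RaptorKO 1 or RaptorKO 3, and with the mean of its probe sets (0.30, adjusted p = 0.12). Ribosomal protein transcripts were slightly higher as a group, with 52 of 60 positive, a median of 0.071 and 0 called members over all genes or adjusted over the list alone; Rpl12 differed by 0.28 and Rpl13a by 0.22. This list passed camera (adjusted p = 0.000435, and adjusted p = 0.724 with an estimated correlation), with medians of 0.11 within replicates 1 and 2 and 0.037 within replicates 3 and 4. Markers of myeloid cells (median 0.24) and of conventional CD4 T cells (median -0.23) shifted by more. Ribosome biogenesis and MYC targets had 0 called of 41 by either count (Cdk4 0.39; median 0.065, camera adjusted p = 0.0637), and passed without WT 1 (0.077) or RaptorKO 4 (0.11). Their median was smaller without WT 2 (0.033), WT 3 (0.043) or RaptorKO 2 (0.031, camera adjusted p = 0.261). Myc itself differed by 0.37 (SE 0.11, adjusted p = 0.138).

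In the lysosome and autophagy list, the protease Ctsl rose by 0.81 (SE 0.16, adjusted p = 0.0284; 0.53 with the mean of its probe sets), and the lysosomal membrane protein Lamp1 rose by 0.46 (adjusted p = 0.041). These were 2 called of 37 tested members, or 8 adjusted over the list alone, all higher. The median was 0.027, with 22 members positive and 15 negative. For the list camera gave adjusted p = 0.0449, and adjusted p = 0.724 with an estimated correlation. The median turned to -0.019 without WT 2, and the call ended without WT 1 (0.034, camera adjusted p = 0.0788) or RaptorKO 2 (0.0042, camera adjusted p = 0.171) and within replicates 3 and 4 (0.025, camera adjusted p = 0.426), but not within replicates 1 and 2 (0.16, camera adjusted p = 0.0145). It also ended with array weights (0.0036, camera adjusted p = 0.126) and with macrophage markers as a covariate (0.039, camera adjusted p = 0.121). Without RaptorKO 1 the median was 0.071. Ctsl lost its call without WT 2, WT 3, WT 4 (0.75, adjusted p = 0.0944) or RaptorKO 1, and Lamp1 without any single array but RaptorKO 4 (highest adjusted p = 0.112, 0.46 without WT 4). Macrophage transcripts also had a higher mean in RaptorKO, with a mean of 4 markers of 5.92 ± 0.79 in WT and 6.54 ± 0.61 in RaptorKO (SD, n = 4).

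Trafficking receptors were lower on balance. The integrin chains Itgb1 (-0.70, SE 0.11, adjusted p = 0.00566) and Itga4 (-0.68) and the chemokine receptor Ccr4 (-0.73) fell, while the gut-homing receptor Ccr9 (0.74) rose. The remaining called members, Ccr8 (0.90) and Gpr15 (-0.76), were named after their values were seen. In total 2 were higher and 4 lower of 21 tested homing receptors, or 2 and 12 adjusted over the list alone, with a median of -0.28, -0.21 within replicates 1 and 2 and -0.36 within replicates 3 and 4. The camera test passed (adjusted p = 1.16e-06, and adjusted p = 0.218 with an estimated correlation). Markers of conventional CD4 T cells (median -0.23, 14 of 16 negative) and of myeloid cells (median 0.24, 17 of 19 positive) also shifted between genotypes. The former include Ccr9. Ccr4 lost its call without WT 1 (-0.70, adjusted p = 0.0929), WT 4, RaptorKO 1 or RaptorKO 3.

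Genes of naive and quiescent T cells had a negative change in all 22 tested members, with a median of -0.18. Btg2, an antiproliferative factor, fell by 0.54 (adjusted p = 0.0184) and was the only called member, with 2 lower adjusted over the list alone; its call ended without WT 1, WT 3, WT 4 (-0.52, adjusted p = 0.0717), RaptorKO 1 or RaptorKO 3. These genes passed camera (adjusted p = 1.01e-05, and adjusted p = 0.724 with an estimated correlation), with medians of -0.15 within replicates 1 and 2, -0.28 within replicates 3 and 4 and -0.27 without RaptorKO 2. The same markers of conventional CD4 T cells (median -0.23) and of myeloid cells (median 0.24) also shifted between genotypes. The former share the tested members Actn1 and Igfbp4 with the naive and quiescence list. In the mitosis list 26 of 33 members were positive with a median of 0.10, and 0 were called over all genes or adjusted over the list alone; Kif23 differed by 0.57 and Prc1 by 0.33. Mitosis had a camera adjusted p = 0.01, and adjusted p = 0.724 with an estimated correlation, and was not called without WT 1 (0.086, camera adjusted p = 0.0956) or with the 60th percentile filter (0.14, camera adjusted p = 0.0508). Without WT 4 its median was 0.16 and without RaptorKO 2 it was 0.066. Myeloid markers (median 0.24, 17 of 19 positive) were also higher in RaptorKO. With macrophage markers as a covariate the mitosis median was 0.053 and its call ended (camera adjusted p = 0.151). Its median was 0.23 in replicates 1 and 2 (camera adjusted p = 0.0116) and 0.016 in replicates 3 and 4 (camera adjusted p = 0.426). In the list of G1/S and DNA replication, the uracil glycosylase Ung (0.55) and the chromatin assembly subunit Chaf1b (0.47) rose and the transcription factor E2f2 (-0.91) fell, 3 called of 33 by both counts. That list did not pass (median 0.070, camera adjusted p = 0.0637), and its median was -0.00025 without WT 2 and -0.0058 in replicates 3 and 4. It passed without WT 3, WT 4 or RaptorKO 1 (0.12, camera adjusted p = 0.0186). Chaf1b lost its call without any single array (highest adjusted p = 0.116, 0.46 without WT 1) and with the mean of its probe sets (0.18, adjusted p = 0.375), Ung without WT 2, WT 3, WT 4 (0.53, adjusted p = 0.0836), RaptorKO 1 or RaptorKO 4, and E2f2 without WT 1, WT 3 (-0.90, adjusted p = 0.0809), WT 4, RaptorKO 1 or RaptorKO 3.

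**Figure D3:**
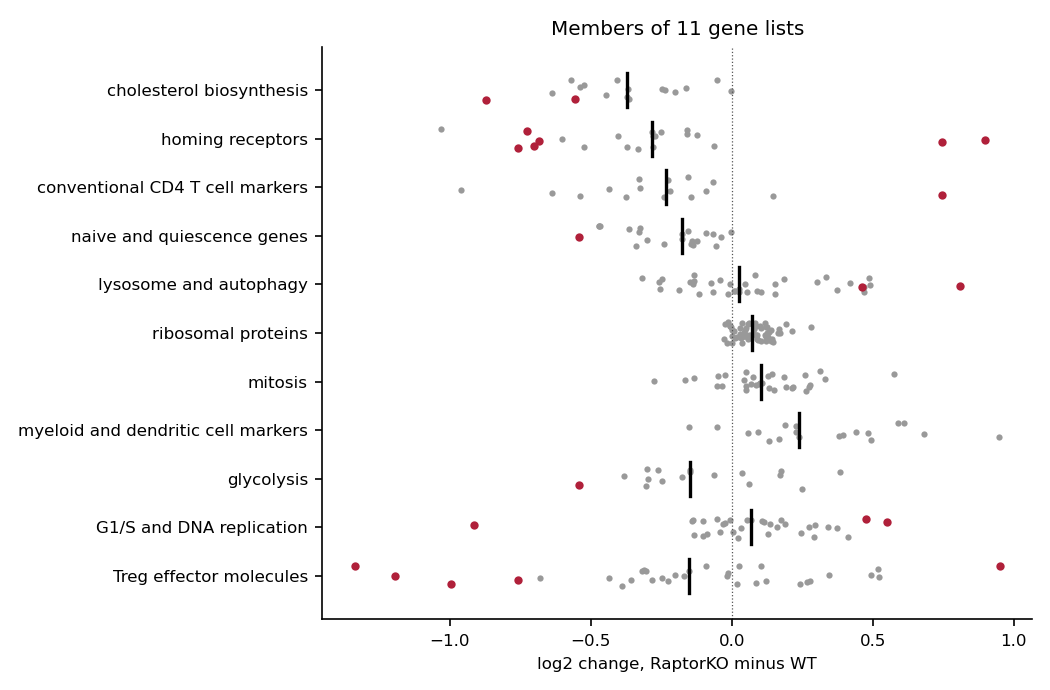
Change of each tested member (x axis, log2, RaptorKO minus WT) in 11 gene lists, with members called over all genes in red, other members in grey and the list median as a black bar. All cholesterol biosynthesis and naive or quiescence members lie below 0, with medians of -0.37 and -0.18, while ribosomal proteins cluster just above 0.

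Activation and signalling lists held single changes. Bhlhe40, a transcription factor induced on T cell activation, rose by 1.48 (SE 0.13, adjusted p = 0.000199), and the NF-kappaB subunit Rel rose by 0.52, which made 2 of 25 T cell receptor activation genes, or 6 higher and 3 lower adjusted over the list alone (median 0.052, camera adjusted p = 0.0645). The list passed without WT 3 (0.073) or RaptorKO 3 (0.12) and within replicates 1 and 2 (0.21, camera adjusted p = 0.0124), while its median was -0.092 within replicates 3 and 4. It was 0.026 without WT 2, 0.021 without WT 4 and 0.0040 without RaptorKO 2 (camera adjusted p = 0.226). Rel lost its call without any single array (highest adjusted p = 0.108, 0.51 without RaptorKO 1). The antiviral gene Rsad2 (0.95) rose and the nuclear body gene Sp100 (-0.43) fell among 28 type I interferon response genes, with 1 higher and 3 lower adjusted over the list alone; the median was -0.082, the mean 0.031 and the camera adjusted p = 0.974. Sp100 lost its call without any single array but RaptorKO 2 (highest adjusted p = 0.14, -0.41 without WT 3). Bcl2l11, the proapoptotic factor Bim, fell by 0.83 (SE 0.14, adjusted p = 0.00945) and was the only called member of 22 apoptosis regulators by both counts (median -0.0015, camera adjusted p = 0.625). Helper T cell cytokines and lineage factors (Stat4 -0.51, Cd40lg -0.32), IL-2 and STAT5 targets (Ahr 0.47), the unfolded protein response (Edem1 -0.47, Dnajb11 -0.36) and immediate early genes (Hsph1 -0.53, Jun -0.32) had 0 called members by either count. Their medians were -0.052, -0.036, -0.070 and -0.15, with camera adjusted p = 0.801, 0.958, 0.121 and 0.212. For immediate early genes the median was -0.062 without WT 1. With the mean of its probe sets Ahr differed by 0.81, and it was called in 1 alternative (lowest limma adjusted p = 0.0393).

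Markers of other cells that a CD4+CD25+ sort could carry were measured in the same way. Myeloid and dendritic cell markers were higher as a group in RaptorKO, with 17 of 19 positive and a median of 0.24. However, 0 were called over all genes or adjusted over the list alone. Lyz2 differed by 0.61 (0.39 to 0.78 without single arrays) and Marco by 0.38 (0.33 to 0.48). The list had a camera adjusted p = 0.00049, and adjusted p = 0.724 with an estimated correlation. It was not called without WT 1 (0.14, camera adjusted p = 0.0956) or with macrophage markers as a covariate (0.046, camera adjusted p = 0.269). That covariate is the mean of C1qa, C1qb, C1qc and Mpeg1, which are members of this list. The smaller median and lost call with it are therefore partly built in. The myeloid median was 0.37 without RaptorKO 1, 0.28 within replicates 1 and 2 and 0.31 within replicates 3 and 4. Erythroid and platelet markers included Hbb-b2 (1.22, adjusted p = 0.0821) and Hba-a1 (1.10), with 0 called of 11 and 2 higher adjusted over the list alone (median 0.12, camera adjusted p = 0.0608); that list passed without WT 4 (0.091), RaptorKO 1 (0.14) or RaptorKO 2 (0.088). Its median was 0.035 without RaptorKO 4 (camera adjusted p = 0.223). Hbb-b2 differed by 1.80 within replicates 1 and 2 and by 0.64 within replicates 3 and 4 (limma interaction, adjusted p = 0.441). For Hba-a1 these were 1.84 and 0.37 (limma interaction, adjusted p = 0.385). Conventional CD4 T cell markers had a median of -0.23 with 14 of 16 negative, but their only called member over all genes, Ccr9, rose; 1 was higher and 7 lower adjusted over the list alone. That list passed camera (adjusted p = 0.000435, and adjusted p = 0.475 with an estimated correlation), within replicates 3 and 4 (-0.36, camera adjusted p = 0.000369) but not within replicates 1 and 2 (-0.12, camera adjusted p = 0.138). With macrophage markers as a covariate Icos, Cyp51, Psat1, Chaf1b, Btg2, Ccr4, Rel, Sp100, Lamp1 and Cd72 lost their calls, with adjusted p from 0.0568 (Btg2) to 0.12 (Rel). Over all alternatives, this covariate included, these genes kept direction. Falls spanned -0.88 to -0.63 for Icos, -0.65 to -0.46 for Cyp51 and -0.74 to -0.47 for Psat1. They spanned -0.64 to -0.44 for Btg2, -0.81 to -0.61 for Ccr4 and -0.47 to -0.34 for Sp100. Rises spanned 0.18 to 0.51 for Chaf1b, 0.37 to 0.67 for Rel, 0.41 to 0.52 for Lamp1 and 0.50 to 0.83 for Cd72.

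Among B cell markers Cd72 (0.66) rose and the class II gene H2-Ob (-1.01) fell, 2 of 13 by both counts (median 0.20, camera adjusted p = 0.111); the list passed without WT 2 (0.30) or RaptorKO 2 (0.22). The B cell median was 0.074 without WT 1 (camera adjusted p = 0.621), 0.11 without WT 4 or RaptorKO 4, and 0.31 without RaptorKO 3 (camera adjusted p = 0.0927). Cd72 lost its call without WT 1 (0.58, adjusted p = 0.0889), WT 2, WT 4, RaptorKO 1, RaptorKO 2 or RaptorKO 4. The chemokine Xcl1 (1.23) rose among 11 CD8, NK and gamma-delta T cell markers, with 2 higher and 1 lower adjusted over the list alone; the median was -0.20 and the mean -0.051 while camera pointed up (adjusted p = 0.993). That median was -0.011 without WT 2 (camera adjusted p = 0.488). Pecam1, the adhesion molecule CD31, fell by 0.89 among 8 stromal and endothelial markers and was the only called member by both counts (median -0.0083, camera adjusted p = 0.663), a call that ended without WT 1, WT 3 or WT 4 (-0.88, adjusted p = 0.0676). Plasma cell markers had 0 called of 7 and 1 lower adjusted over the list alone (median -0.090, camera adjusted p = 0.492). Irf4 differed by -0.39 (-0.49 with the mean of its probe sets) and was called in 1 alternative (lowest limma adjusted p = 0.0241). Jchain differed by 0.79, with 1.68 within replicates 1 and 2 and -0.11 within replicates 3 and 4 (limma interaction, adjusted p = 0.314).

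Sex-linked transcripts divided the arrays within both genotypes. Xist, the RNA of the inactive X chromosome, was 10.90, 10.88, 11.18 and 11.15 in WT 1, WT 2, RaptorKO 1 and RaptorKO 2 but between 5.04 and 5.62 in the other 4 arrays. The Y-linked gene Eif2s3y read 2.92, 3.36, 3.06 and 3.32 in the former and between 7.70 and 8.19 in the latter. Each genotype therefore held 2 arrays of either pattern, and the 4 sex-linked genes tested between genotypes had 0 calls by either count (Kdm5d -0.20, Uty -0.10; median 0.013, camera adjusted p = 0.974). The macrophage gene C1qa was also higher in replicates 3 and 4, by 1.27 (SE 0.13, limma adjusted p = 0.00169 with genotype in the fit), as were C1qc (1.34), Fos (1.18) and Hmox1 (1.14). In all 18 genes differed between the 2 sets of replicates.

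**Figure D4:**
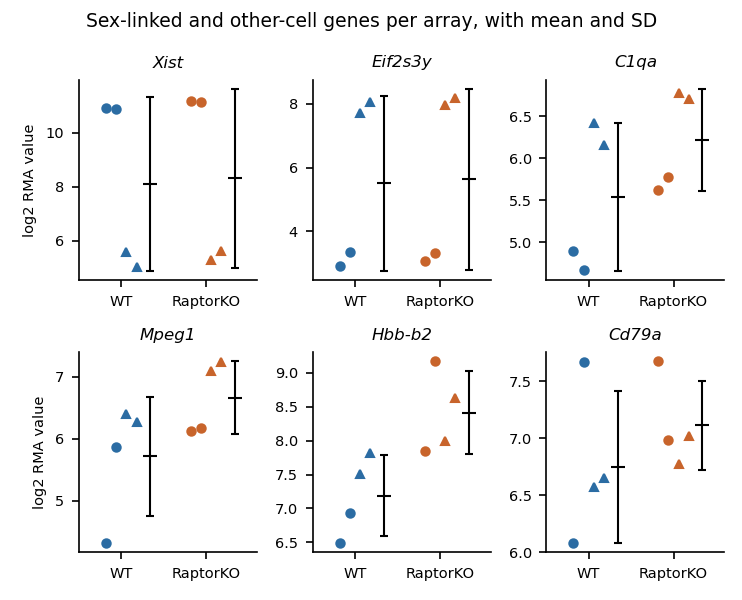
Log2 values of 6 genes on each array, with circles for replicates 1 and 2, triangles for replicates 3 and 4, and bars for the mean and SD of 4 arrays; y axes do not start at 0. Xist and Eif2s3y separate circles from triangles in both genotypes, and C1qa is higher in triangles than in circles within each genotype.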

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

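The tests of the sex pattern and of macrophage RNA and the counts over balanced splits in this part were chosen after the result was seen; the counts over all splits of the arrays were planned before.

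Several values stood far from the other 3 of their group, by the size of the gap to the nearest relative to the group's range. There were 12 such cases among 174 groups of 4 values, and chance gives about 1 in 20. In RaptorKO 2 the value of Rnf157 was 8.58 (others 7.73 to 7.78), that of Swap70 was 8.27 (lowest of the others 7.98) and that of Dnajb11 was 9.26 (8.87 to 8.93). In WT the values were 7.65 for Chst2 in WT 4 (others 7.99 to 8.03), 8.68 for Nrp1 in WT 2 (9.23 to 9.31), 7.25 for Acss2 in WT 3 (6.89 to 6.94), 4.50 for Kif23 in WT 1 (5.07 to 5.13), 6.17 for Ahr in WT 1 (6.70 to 6.78) and 9.61 for Jun in WT 2 (10.10 to 10.14). In RaptorKO they were 5.003 for Kif23 in RaptorKO 3 (5.63 to 5.75), 9.05 for S100a6 in RaptorKO 4 (8.26 to 8.38) and 9.42 for Sp100 in RaptorKO 1 (9.61 to 9.64). Probe sets with no gene listed were outside the comparison of genes, and 15 of 8331 tested differed between genotypes (limma, adjusted over these probe sets), 7 higher and 8 lower.

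Over all 35 splits of the 8 arrays into 4 and 4, the genotypes gave 224 changed genes. The highest other split, replicates 1 and 2 against 3 and 4, gave 5. Only 1 of 35 splits, the real one, gave as many, a share of 0.029 and the lowest that this test can give. It argues against chance if the 8 arrays are interchangeable, which the 2 sets of replicates put in doubt. Of the 35 splits, 18 keep 2 arrays of replicates 1 and 2 on each side; they are too few for a share under 0.05, and among them the highest other count was 1. For genes in a single direction, 1 of 35 splits reached the 94 higher and 1 reached the 130 lower, with 4 as the highest other value. A difference in sex between genotypes is argued against, since each genotype held 2 arrays of the female pattern and a fit with a term for the 2 sets of replicates called 248 genes, 214 of them shared with the 224. No gene passed an interaction of genotype with these sets in limma. However, 1304 of 11413 had an unadjusted interaction p under 0.05, a larger share than the 0.05 that chance gives. For genotype in the main fit 1488 had an unadjusted p under 0.05. A difference in the change between the sexes or batches of mice was therefore not detected for any single gene and stays open.

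The genotypes called 8 gene lists, while 14 of 35 splits, 8 of the 18 balanced ones among them, called as many and the highest other split called 10, so chance cannot be excluded for the number of lists. Cholesterol biosynthesis had a smaller camera p in the real split than in any other of the 35 (4.61e-10 against 2.37e-06 for the next). A share of 1 of 35 is the lowest that this test can give, and it was not adjusted over lists. It argues against chance for that p, at the preset correlation, only if the 8 arrays are interchangeable. Among the 18 balanced splits, too few for a share under 0.05, the smallest other was 3.23e-06. With an estimated correlation the list was not called (adjusted p = 0.218; range over alternatives 6.09e-10 to 0.218). The mitosis list had 7 of 35 splits with a camera p as small (0.00201 against 1.01e-07 for the smallest other), so for it chance cannot be excluded.

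In the lysosome and autophagy list, 8 members called over the list alone were higher in RaptorKO, where macrophage markers were higher too, so RNA from macrophages, which a CD4+CD25+ sort should remove, could raise both. These 8 differed by a median of 0.47 between genotypes. Between replicates 1 and 2 and replicates 3 and 4 they differed by a median of 0.013, from -0.34 to 0.11, although C1qa, C1qb, C1qc and Mpeg1 differed there by a median of 1.20 against 0.56 between genotypes. These 8 were picked by a genotype fit with no term for the replicate sets, where a large difference between the sets makes a call less likely. The small median of 0.013 is therefore partly built in and does not decide whether macrophage RNA contributed. With the markers as a covariate, the list's median was 0.039 against 0.027 without it, and the list was not called (camera adjusted p = 0.121; range over alternatives 0.0139 to 0.724), but that covariate also follows the replicate sets, with marker means of 4.96 to 6.02 in replicates 1 and 2 and 6.52 to 7.09 in replicates 3 and 4.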

How the results depend on the processing

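Fits with a term for, or within, replicates 1 and 2 against 3 and 4, and with a macrophage covariate, were chosen after seeing the data. Over 2042 comparisons of a named gene with an alternative, 1814 kept direction and side of the threshold, 195 lost the call, 24 gained it and 9 changed sign. For gene lists these were 698, 26, 55 and 61 of 840. None of the 48 called named genes changed sign in any alternative where it was tested. Of these, 29 stayed called in all 8 fits that left out an array, while 18 lost the call in at least 1 of them. Gbp2b and Fgl2, which passed the filter on the WT arrays only, were not tested where a WT array was left out. The cause of the shifts below was not tested, except that fits with fewer arrays have less power by construction. Signal near background limits dim genes: 17097 genes were tested without the filter and 11413 with it.

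Counts of genes changed were 370 (147 higher, 223 lower) with an intensity trend. Genes lower numbered 205 with array weights and 82 at 1.5-fold. Replicates 1 and 2 gave 11 (9 higher, 2 lower) and replicates 3 and 4 gave 128 (40 higher). With the macrophage covariate 176 genes changed (89 higher, 87 lower), and 139 of them were shared with the main fit. Leaving out arrays gave 102 to 250 changed, 56 to 83 higher, 46 to 172 lower and 7 to 14 lists. Lists called numbered 15 with no filter, 0 with an estimated correlation and 2 with fry.

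With the replicate block, 175 genes changed (90 higher, 85 lower), 150 shared with the 224, and 11 lists were called. Deviations of arrays with the same number correlated at 0.157, -0.153, 0.106 and 0.0259, and not every array correlated best with its own number, so the numbers were not taken to pair the samples.

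For 5 lists, values are camera adjusted p unless fry is named. Cholesterol biosynthesis lost its call only with an estimated correlation (-0.37, 0.218; range over alternatives 6.09e-10 to 0.218). Mitosis (range 0.000305 to 0.724) lost its call with the 60th percentile filter (0.14, 0.0508), an estimated correlation (0.10, 0.724), fry (0.10, 0.394), replicates 3 and 4 (0.016, 0.426) and the macrophage covariate (0.053, 0.151), and spanned 0.066 to 0.16 without single arrays. Glycolysis gained a call with no filter (-0.16), a trend (-0.15), array weights (-0.20) and replicates 3 and 4 (-0.19), and spanned -0.20 to -0.13 without single arrays. Effector molecules gained one with the replicate block (-0.15), no filter (-0.12) and the macrophage covariate (-0.073), spanned -0.16 to -0.027 without single arrays, and turned to 0.0052 in replicates 1 and 2. G1/S and DNA replication turned to -0.0058 in replicates 3 and 4 and spanned -0.00025 to 0.12 without single arrays.

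Among the other lists, every call was lost with an estimated correlation, and all but homing receptors lost it with fry: ribosomal proteins (fry adjusted p = 0.068), naive and quiescence genes (0.131), conventional CD4 T cell markers (0.068), lysosome and autophagy (0.394) and myeloid markers (0.394). Lysosome and autophagy also lost its call with array weights (0.126), in replicates 3 and 4 (0.426) and with the macrophage covariate (0.121). Conventional CD4 T cell markers lost theirs in replicates 1 and 2 (0.138), and myeloid markers with the macrophage covariate (0.269). The loss for myeloid markers is partly built in, since the covariate is a mean of members of that list. Calls were gained by ATF4 targets with the replicate block, no filter, array weights, the term for the replicate sets (0.048) and replicates 3 and 4, and by oxidative phosphorylation with no filter, 75th percentile centring, a trend, array weights and replicates 3 and 4. Ribosome biogenesis gained one with the mean of probe sets, no filter, quantile normalization, a trend and the macrophage covariate (0.016), and erythroid markers with the replicate block and no filter. T cell receptor activation gained one with no filter, quantile normalization and replicates 1 and 2, fatty acid synthesis and the unfolded protein response with the mean of probe sets, B cell markers with array weights, and immediate early genes with the macrophage covariate.

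All other list medians that changed sign belonged to lists not called, apart from lysosome and autophagy (-0.019 to 0.071 without single arrays). Without single arrays the ranges were -0.045 to 0.0098 for apoptosis regulators, -0.091 to 0.014 for helper cytokines, -0.067 to 0.011 for IL-2 and STAT5 targets, -0.023 to 0.059 for mitochondrial biogenesis, -0.018 to 0.066 for mTOR regulators, -0.073 to 0.043 for nucleotide synthesis, -0.81 to 1.22 for sex-linked genes, -0.060 to 0.035 for stromal markers, -0.018 to 0.062 for translation and -0.096 to 0.014 for Treg identity, and for genes -0.032 to 0.077 for Il2ra, -1.01 to 0.58 for Kdm5d and -0.52 to 0.36 for Uty. The mean of probe sets gave -0.081 for Il2ra, 0.0077 for nucleotide synthesis, 0.0090 for fatty acid oxidation and -0.038 for sex-linked genes. CD8 and NK markers were 0.012 with no filter and 0.095 with the 60th percentile filter. Quantile normalization gave 0.020 for nucleotide synthesis, 0.019 for Treg identity and 0.021 for apoptosis regulators, which were 0.0019 with 75th percentile centring. Array weights gave -0.013 for translation, -0.0032 for mitochondrial biogenesis, 0.023 for stromal markers and -0.085 for sex-linked genes.

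In replicates 1 and 2 the medians were 0.018 for the TCA cycle, 0.064 for oxidative phosphorylation, 0.11 for nucleotide synthesis, 0.12 for Treg identity, 0.074 for helper cytokines, 0.012 for IL-2 and STAT5 targets, 0.054 for type I interferon, 0.16 for fatty acid oxidation and 0.028 for the unfolded protein response. In replicates 3 and 4 the values were -0.057 for Il2ra, -0.05 for Dut, -0.11 for Jchain, -0.062 for translation, -0.092 for T cell receptor activation, -0.035 for mTOR regulators, -0.022 for mitochondrial biogenesis and 0.033 for stromal markers. The macrophage covariate gave 0.014 for nucleotide synthesis, 0.011 for Treg identity, 0.0054 for fatty acid oxidation, 0.00049 for apoptosis regulators and -1.72 for sex-linked genes. With it the sex-linked list was called (camera adjusted p = 0.016; range over alternatives 0.016 to 0.998), as were Kdm5d (-2.33, adjusted p = 0.00983; range 0.00983 to 0.984) and Uty (-1.23, adjusted p = 0.0294; range 0.0294 to 0.984), so this covariate is not separate from the replicate sets.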

Other observations

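The gene groups and tests in this part were chosen after the genes that prompted them were seen; of the tests, that on the neighbours of Rptor was set before those values were looked at. The set of other interferon-gamma targets was made before its values were seen and narrowed afterwards.

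Interferon-inducible GTPases, the families of GBP and IRG proteins that act against intracellular pathogens, included several called genes. Of 13 tested, 12 had a negative change, with a median of -0.46, and 8 were called in the limma fit over all genes. Gbp3 fell by 1.11 (SE 0.14, adjusted p = 0.00243), Iigp1 by 0.67, Gbp2 by 0.57, Tgtp1 by 0.50, Igtp by 0.46, Gbp7 by 0.46 and Ifi47 by 0.44. Gbp2b differed by -1.67, with RaptorKO values (3.88 to 4.37) under the filter's percentile, so that size is uncertain. The group was assembled around these 8, which had been seen to fall, so its count and median are not independent evidence. Of the 5 members not seen before, 0 were called in limma and 1 had an unadjusted p under 0.05; they had a median of -0.15, from -0.40 (Irgm1) to 0.073 (Gbp4).

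A single segment of chromosome from another strain would place these genes together, but the 8 lie on 3 chromosomes. Igtp, Tgtp1 and Ifi47 lie on chromosome 11, as does Gaa, a neighbour of Rptor, and a segment that holds these 3 was not tested. For the GBP part it stays open too. The 4 called GBP genes all lie on chromosome 3, while Gbp8, Gbp10 and Gbp4 on chromosome 5 differed by -0.15, -0.099 and 0.073. Of the 40 nearest tested genes around the GBP genes on chromosome 3, 0 were called in limma and 5 had an unadjusted p under 0.05, which does not decide it. Probe sets shared between paralogs within a family were not tested. A lower response to interferon-gamma is a candidate explanation, since 20 other targets had a median of -0.090 (camera p = 0.00659, and p = 0.125 with an estimated correlation). None was called in limma, and 5 had an unadjusted p under 0.05. With 4 receptor and kinase genes of the pathway, which are not targets but were in the set at first, the median was -0.071 (camera p = 0.0182, and p = 0.174 with an estimated correlation). It is a small shift that rests on the preset correlation and leaves this a hypothesis.

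Several lysosomal genes outside the fixed list were called: Tpp1 (0.69), Gaa (0.77), Atp6ap2 (0.47) and Clcn6 (0.44) rose while Man2b1 (-0.45) fell. Whether a wider lysosomal programme could be raised was tested on 25 further lysosomal genes whose values had not been seen. Of the 25, 17 were positive, none was called in limma and 6 had an unadjusted p under 0.05. These 6 went both ways. Atp6v0b (0.41), Clcn7 (0.39) and Atp6v1b2 (0.28) were higher, and Atp6v1d (-0.45), Scarb2 (-0.42) and Lipa (-0.34) were lower. The median of the 25 was 0.098 and did not pass camera, which leaves the question open.

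Gaa, the lysosomal alpha-glucosidase, is a neighbour of Rptor in the reference gene order and rose by 0.77 (SE 0.16, adjusted p = 0.0312). An effect of the altered locus on other nearby genes might show as more calls around it. Of the 40 nearest tested genes, 20 on each side, 2 were called, Gaa and Tepsin (-0.46). Since Gaa prompted the test, the count without it was 1 of 39 against 0.762 by chance (exact hypergeometric p = 0.537), which does not decide it.

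Among probe sets without a gene name, the largest differences were -1.78 (limma adjusted p = 0.002) and -1.57 in the lower direction and 1.16 and 1.13 in the higher.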
